A study of Mus musculus with 9 samples.

How the data were processed

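The data are microarray measurements of motor neurons cut by laser microdissection from frozen sections of male C57BL/6J mice at postnatal day 7. Per the labels' protocols, 12 µm sections were stained with cresyl violet, about 200 motor neurons of each pool were collected from each of 3 animals, and at least 1.5 ng of RNA was amplified with a whole-transcript kit, labelled with biotin and hybridised to Affymetrix Mouse Genome 430 2.0 arrays. The 3 pools were the motor neurons of the fifth lumbar segment (L5), the oculomotor nucleus of the midbrain (OMN) and the dorsolateral nucleus at the sixth lumbar level (DL). Each pool had 3 arrays. The labels do not say how motor neurons were recognised beyond the stain.

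The authors deposited 1 table of processed intensities, with 1 value for each of 45101 probe sets on each array. The deposited intensity values were on a linear scale, and the mean of each array after removal of 2% of its values at each end was 250.0, so that each array had been scaled to one target. The software that made them is not given in the sources used here. Upper quartiles of the arrays lay within 0.14 of one another on the log2 scale, and the values were used as deposited. A scaled array carries no information on the total amount of RNA per cell, and a change in many genes at once would shift all others the opposite way. The number of arrays limits the precision.

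Of the probe sets, 64 were controls and were left out of the tests. Among the other 45037, 34945 named 1 gene in the platform annotation, 932 named several and 9160 named none. Gene IDs of 34741 probe sets were found in the RefSeq gene table and 0 symbols changed. Each gene was represented by its probe set with the highest mean over the 9 arrays, which left 18193 genes, 9010 of them with more than 1 probe set. No genome coordinates were used here. The highest value of 27 control probe sets for unspiked bacterial transcripts on any array, 18.3, was taken as the noise level, a choice made after the values had been seen. 2654 genes did not exceed it on any array. Where a gene lay at or below 18.3 on all 3 arrays of a pool, the difference from a brighter pool is given as a lower bound, the geometric mean of the bright pool over the noise level. Where the mean of a pool lay under 18.3 but an array did not, the bound was taken after values under 18.3 had been raised to it.

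Intensities were converted to log2(intensity + 16), and differences in log2 are on that scale, which understates the change of dim genes. All 9 arrays were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), with the pool as the factor and the replicate number in the sample titles as a block, since the protocol states that each animal gave all 3 pools. No label states that equal numbers mean the same animal. P-values were adjusted by the Benjamini-Hochberg method over the 18193 genes of each comparison, and genes with an adjusted p under 0.05 are called higher or lower. The comparisons were L5 with OMN, L5 with DL, DL with OMN, L5 with the mean of OMN and DL, and the genes that differed from L5 in the same direction in both other pools. The fit shares 1 estimate of the spread per gene over the 3 pools. Errors of log2 differences are standard errors (SE) of the fit, and errors of intensities are SD over the 3 arrays of a pool.

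Before the data were examined, 33 gene lists with 809 symbols were written down, covering motor neuron identity, positional genes, receptors, channels, metabolism, genes linked to amyotrophic lateral sclerosis (ALS) and markers of other cell types. 695 of the symbols were matched, 4 of them through a synonym. The lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. With the estimate, p also rose for lists whose estimated correlation lay below 0.01. For the inhibitory interneuron markers between L5 and DL the estimate was -0.127, and the unadjusted camera p went from 0.00153 to 0.0306. A call lost with the estimate therefore need not come from correlated members. For each list the number of its members past the threshold is given with p adjusted over all genes and, in those words, adjusted over the list alone. The rule for named genes was also fixed then. It took the 10 largest differences in each direction among called genes with the same sign in all 3 pairs of equal number, passing over provisional gene names, up to 4 members of each list with the smallest p, a panel of motor neuron genes where measured, and the 10 genes in each direction with the largest smaller difference among those that differed from both other pools. Some genes that could be of interest are not reported here.

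The scripts were tested on simulated arrays with 200 planted differences among genes with a mean over 50. For L5 against OMN, 13.4% of planted log2 differences of 1 were recovered, 94% of those of 2 and 100% of those of 3, and 8% of the calls were false. For L5 against DL the shares were 13.4%, 97% and 100% with 1.41% false calls, and for DL against OMN 14.9%, 94% and 98.5% with 4.17%. These simulations gave every pool the same spread.

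The alternatives tried were fits without the block or with it as a random effect, fits of the compared pools only, quantile normalization, centring on the median, filters on dim genes, the mean of all probe sets of a gene, all probe sets separately, eBayes with a trend and robust variances, array weights, pseudocounts of 1 and 64, and each array left out in turn. A fit without DL arrays 1 and 3, and a fit with the log2 ratio of the 3' to the 5' Gapdh control probe set as a covariate, were added after seeing the data. Tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15, and figures drawn with matplotlib 3.10.9.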

Results

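Gene expression was measured in motor neuron pools that differ in their vulnerability in ALS, a disease in which spinal motor neurons die while those that move the eyes and those of the pelvic sphincters are relatively spared. L5 stands here for the spinal motor neurons of a limb level, OMN for the oculomotor nucleus, which drives eye muscles, and DL for the dorsolateral nucleus of the lumbosacral cord. Each pool was measured on 3 arrays. Between 67.0% and 71.5% of the 18193 genes exceeded the noise level on an array, and the median intensity was 32.0 to 34.3 in L5, 33.6 to 35.5 in OMN and 26.4 to 29.7 in DL. Replicates of DL differed more from one another than those of the other pools. The median SD of log2 values over 7120 genes with a mean above 200 was 0.294 in DL, 0.204 in L5 and 0.171 in OMN. The fit uses 1 spread for all pools. Its errors for differences with DL can therefore be too small, and those for L5 against OMN too large. The ratio of the 3' to the 5' Gapdh control probe set, a sign of RNA quality, was 3.27, 2.44 and 3.75 on the DL arrays and lay between 2.33 and 2.67 on the others. The same ratio for beta-actin was 0.934, 0.807 and 0.995 on the DL arrays and 0.900 to 0.934 on the others. By beta-actin, DL array 1 did not stand apart. The first principal component of all genes, with 25.9% of the variance, set DL apart, and the second, with 22.2%, set L5 apart.

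L5 motor neurons differed from OMN most in the genes that mark position along the body axis. Hoxc10, a lumbar Hox gene, had an intensity of 4027 ± 519 (SD, n = 3) in L5 and 12.0 ± 7.17 in OMN, near or under the noise level, at least 214-fold higher in L5 (limma adjusted p = 6.71e-05). Hoxd9 was at least 115-fold higher in L5, Hoxa9 at least 88.4-fold and Hoxd10 at least 74.6-fold, each with OMN at the noise level. Aldh1a2, which makes retinoic acid, stood at 2284 ± 414 in L5 and 16.1 ± 16 in OMN. In the other direction Cartpt, which encodes the CART neuropeptide, was at 80.4 ± 3.10 in L5 and 2972 ± 1100 in OMN (log2 difference -4.88 ± 0.27, adjusted p = 0.000458), and Tbx20, a T-box factor of cranial motor neurons, was at least 23.6-fold lower in L5.

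Of 16 measured Hox genes of paralog groups 8 to 13, 10 were higher in L5 than in OMN and 0 were lower, and the same number, 10, was obtained adjusted over the list alone (camera adjusted p = 8.42e-17, and adjusted p = 0.0238 with an estimated correlation). Hoxa11, Hoxd11, Hoxd8 and Hoxa10 were among them. Of 17 Hox genes of groups 1 to 7, 6 were higher and 11 were higher adjusted over the list alone (adjusted p = 3.46e-11, and adjusted p = 0.0269 with an estimated correlation). Hoxc4 was at 209 ± 64.9 against 4.93 ± 4.52 and Hoxa5 at 157 ± 18.8 against 3.83 ± 2.81. Of 9 transcription factors of the midbrain and oculomotor nucleus, 6 were lower in L5, over all genes and adjusted over the list alone (adjusted p = 7.76e-10, and adjusted p = 0.0272 with an estimated correlation). En1 was at 21.1 ± 8.01 against 279 ± 58.6, En2 at 14.1 ± 13.5 against 271 ± 15.6 and Eya1 at 31.7 ± 6.63 against 374 ± 106. Mnx1, a homeobox factor of spinal motor neurons, was at 128 ± 40.9 in L5 and 1.77 ± 1.10 in OMN.

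Some receptors for inhibitory transmitters differed between L5 and OMN. Of 16 GABA and glycine receptor genes, 4 were higher in L5 and 1 was lower, and 5 and 1 adjusted over the list alone (camera adjusted p = 0.000354, but adjusted p = 0.151 with an estimated correlation). Glra1, the glycine receptor subunit of the adult type, was at 3716 ± 435 in L5 and 161 ± 72.7 in OMN, and Glra2 at 2263 ± 464 and 370 ± 45.3. Gabra5 was higher and Gabrb2 lower in L5, the latter at 247 ± 35.4 against 1575 ± 148. Trhr, the receptor for thyrotropin-releasing hormone, was at 2118 ± 476 in L5 and 111 ± 35.0 in OMN, whereas Htr3a, a serotonin-gated channel, was at 527 ± 95.5 and 2300 ± 16. Among 18 neuropeptide genes 2 were higher and 2 lower, over all genes and adjusted over the list alone, with Nts and Sst higher in L5 and Cartpt and Adcyap1 lower (camera adjusted p = 0.536).

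Of 49 axon guidance genes, 0 were higher in L5 and 8 were lower, with 7 and 13 adjusted over the list alone (camera adjusted p = 0.0197, but adjusted p = 0.288 with an estimated correlation). Sema3e, a secreted semaphorin, was at 77.9 ± 31.3 in L5 and 1543 ± 238 in OMN. Plxna2, Epha6 and Epha7 were also lower, with log2 differences of -1.76 ± 0.19, -2.37 ± 0.21 and -2.50 ± 0.32. Pvalb, a calcium buffer, was at 731 ± 183 in L5 and 5221 ± 154 in OMN (log2 difference -2.84 ± 0.22, adjusted p = 0.00165). Mmp9, a matrix metalloproteinase, was at 640 ± 119 in L5 and 94.2 ± 10.1 in OMN, a log2 difference of 2.56 ± 0.38 (adjusted p = 0.0217) that passed the threshold with 1 of its 2 probe sets. Nrn1, Gngt1, Krt25, Chrm1 and Kcnj5 were among the 10 largest differences with OMN higher.

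Some markers of other cells moved with this comparison. Gfap, an astrocyte filament, was at 325 ± 82.4 in L5 and 18.0 ± 5.34 in OMN, while 13 of the 14 astrocyte markers made no call (camera adjusted p = 0.0432, but adjusted p = 0.288 with an estimated correlation and 0.119 after quantile normalization). Pmp22, a myelin protein of peripheral nerve, was at 2060 ± 176 and 135 ± 37.1. Slc6a5, the glycine transporter of inhibitory neurons, was higher in L5 (551 ± 90.2 against 22.6 ± 14.7), and Gad1 and Gad2, which make GABA, were lower. The catecholamine genes Th, Ddc and Slc6a2 were lower in L5, Th at 15.97 ± 6.28 against 88.9 ± 21.6. In all, limma called 173 genes higher and 219 lower in L5 than in OMN. This balance turned to 210 higher and 196 lower with arrays centred on their medians, 533 and 413 with a trend and robust variances and 62 and 39 with a pseudocount of 1. The count of 392 fell to between 82 and 107 when any one of the 6 L5 and OMN arrays was left out and to 101 with a pseudocount of 1, and it was 946 with a trend and robust variances and 677 with array weights. The Mmp9 call was lost on leaving out any one of those 6 arrays, and 38 of 85 named and called genes kept their call in all alternatives chosen beforehand.

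**Figure D1:**
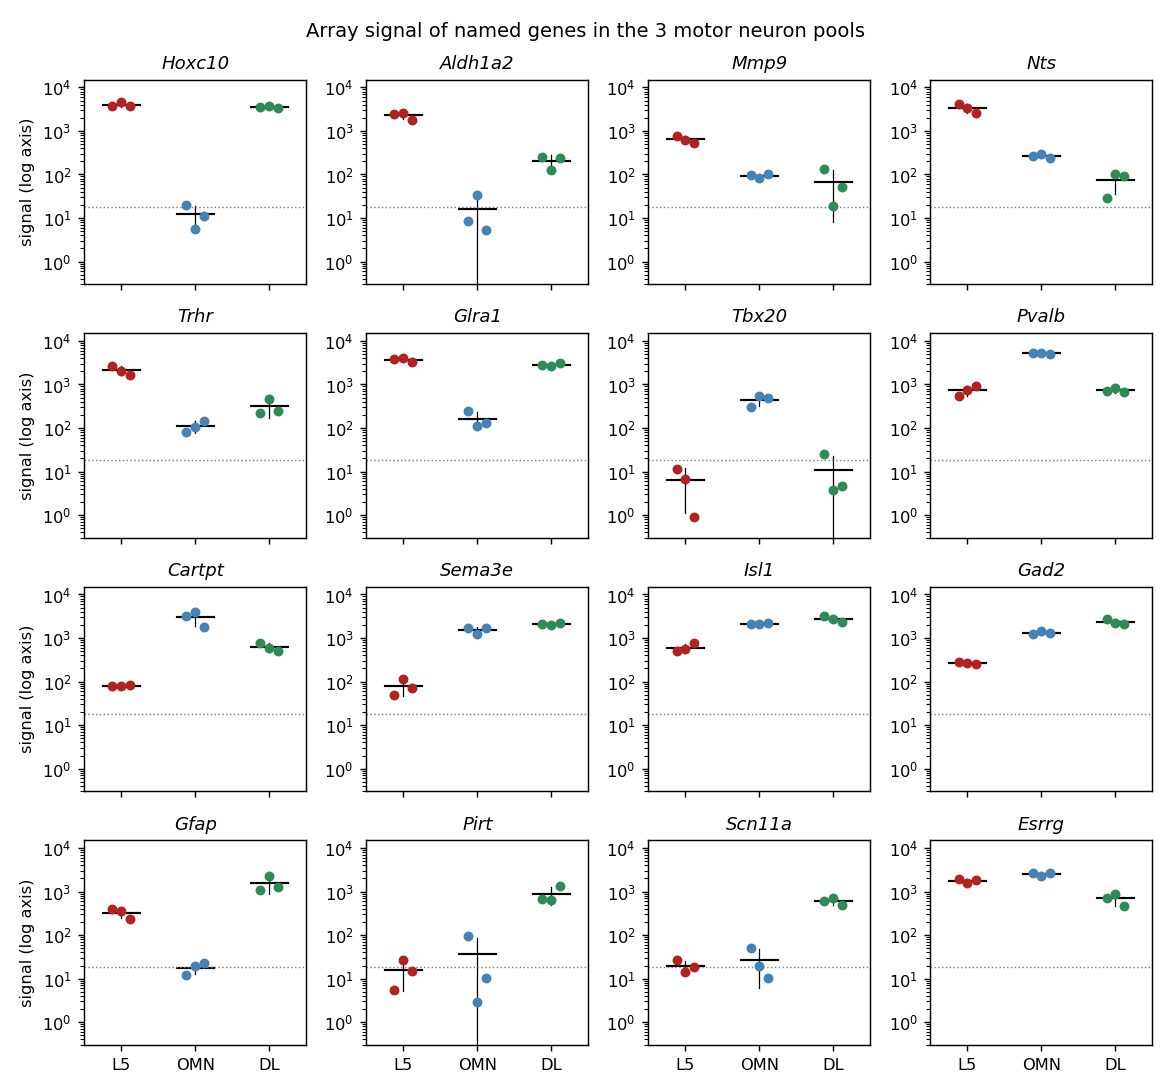
Array intensity (log axis) of 16 named genes in the L5, OMN and DL pools, with points for the 3 arrays of a pool, horizontal lines for their means, vertical bars for the SD (ended at the foot of the axis where the SD exceeds the mean) and a dotted line at the noise level of 18.3. Hoxc10 is near 4027 in L5 and 3558 in DL and below the dotted line on average in OMN, and Pvalb is highest in OMN at 5221.

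L5 and DL, both spinal pools, differed in individual genes, and no list was called by camera with an estimated correlation. Nts, which encodes neurotensin, was at 3413 ± 823 (SD, n = 3) in L5 and 74.2 ± 39.2 in DL, a log2 difference of 5.34 ± 0.37 (limma adjusted p = 0.00268). Hsd17b2, a steroid dehydrogenase, was at 706 ± 103 and 27.3 ± 27.7, and Kcng4, a modifier of potassium channels, at 572 ± 70.6 and 20.1 ± 26.2. In DL the sodium channel gene Scn7a was at least 32.2-fold higher, Pirt, a membrane protein known from sensory neurons, was at 883 ± 404 against 15.4 ± 10.4 in L5, and Scn11a, a sodium channel also known from sensory neurons, at 609 ± 105 against 19.9 ± 6.07. Sema3e was at 77.9 ± 31.3 in L5 and 2082 ± 96.9 in DL.

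Of the 16 Hox genes of groups 8 to 13, 0 were higher and 1, Hoxd11, was lower in L5 than in DL, and 3 and 1 adjusted over the list alone (camera adjusted p = 0.901). Hoxd11 was at 705 ± 202 in L5 and 2014 ± 265 in DL, while Hoxc10 was at 4027 ± 519 and 3558 ± 215 (adjusted p = 0.764). Hoxa3 was also lower in L5, at 160 ± 39.1 against 574 ± 107. Of the 5 fast and alpha motor neuron markers, 2, Mmp9 and Vipr2, were higher in L5, and 3 adjusted over the list alone (camera adjusted p = 0.0154, but adjusted p = 0.277 with an estimated correlation). Mmp9 was at 640 ± 119 in L5 and 68.0 ± 59.7 in DL, a log2 difference of 3.20 ± 0.38 (adjusted p = 0.0107) called with both of its probe sets. Of the 7 slow and gamma markers, 2, Wnt7a and Esrrg, were higher in L5, and 3 adjusted over the list alone (adjusted p = 0.0228, but adjusted p = 0.277 with an estimated correlation). Esrrg, an orphan nuclear receptor, was at 1772 ± 183 against 695 ± 220.

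Some neuropeptide genes differed between L5 and DL. Of 18, 1, Nts, was higher in L5 and 3 were lower, with the same numbers adjusted over the list alone (camera adjusted p = 0.00972, but adjusted p = 0.277 with an estimated correlation). Tac1, the substance P precursor, was at 277 ± 64.9 in L5 and 2314 ± 248 in DL, Cartpt at 80.4 ± 3.10 and 618 ± 134, and Gal, the galanin precursor, at 29.1 ± 14.5 and 174 ± 13.2. Of 34 potassium channel genes, 5 were higher and 2 lower in L5, and 11 and 5 adjusted over the list alone (adjusted p = 0.223). Kcna1 was higher and Kcnv1 lower, the latter at 24.5 ± 1.65 against 262 ± 25.8. The receptor genes Hcrtr2 for orexin and Tacr1 for substance P were higher in L5, as was Uts2, which encodes the peptide urotensin, and the vasopressin receptor gene Avpr1a was lower. Isl1, a LIM homeobox factor of motor neurons, was at 598 ± 134 in L5 and 2717 ± 414 in DL. Ngfr, the low-affinity neurotrophin receptor, was at 163 ± 74.5 and 1052 ± 276, Bdnf at 62.5 ± 33.4 and 343 ± 102, and Calb1, called with 1 of its 4 probe sets, at 95.8 ± 14.1 and 331 ± 105.

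Markers of other cells differed too. Of 15 oligodendrocyte markers 3, Cldn11, Ermn and Ugt8a, were lower in L5 than in DL, and 5 adjusted over the list alone (camera adjusted p = 0.0126, but adjusted p = 0.277 with an estimated correlation). Gfap was at 325 ± 82.4 in L5 and 1550 ± 683 in DL, while the other 13 of 14 astrocyte markers made no call and the median of the list was 0.35 higher in L5 (camera adjusted p = 0.225). Of 8 inhibitory interneuron markers 2 were lower in L5, and 3 adjusted over the list alone (adjusted p = 0.0126, but adjusted p = 0.277 with an estimated correlation), with Gad2 at 269 ± 18.4 against 2340 ± 340. In all, limma called 228 genes higher and 231 lower in L5 than in DL, 459 in sum. The balance was 194 and 298 with arrays centred on their medians (39.4% higher in place of 49.7%), 304 and 232 with the mean of all probe sets and 621 and 526 with a trend and robust variances. The count was 47 when only the L5 and DL arrays were fitted. It was 61 to 254 when any one of the 9 arrays was left out and 62 with a pseudocount of 1. With the Gapdh ratio as a covariate it was 90, and with no replicate block 805. Array weights gave 323 and kept 321 of the 459 calls. Without DL arrays 1 and 3, which left 1 DL array, limma called 0 genes, with 2996 at an unadjusted p under 0.05. Of the named and called genes, 13 of 77, Nts, Sema3e, Scn7a, Scn11a, Gad2, Ngfr and Kcnv1 among them, kept their call in all alternatives chosen beforehand.

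DL differed from OMN in Hox genes and midbrain factors, the only lists called with an estimated correlation. Hoxc10 was at 3558 ± 215 (SD, n = 3) in DL and 12.0 ± 7.17 in OMN, at least 189-fold higher in DL (limma adjusted p = 8.67e-05). Hoxd11 was at least 109-fold higher in DL, Hoxd10 at least 94.4-fold, Hoxa9 at least 77.8-fold and Hoxa3 at least 31.0-fold. Gfap was at 1550 ± 683 in DL and 18.0 ± 5.34 in OMN, at least 73.2-fold higher in DL (adjusted p = 0.000421). On the other side Fign, a microtubule-severing enzyme, was at 29.0 ± 16.8 in DL and 1152 ± 405 in OMN, Sgpp2, a sphingosine phosphate phosphatase, at 23.8 ± 12.2 and 769 ± 86.7, and Tbx20 at 11.1 ± 11.9 and 445 ± 120.

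Of the 16 Hox genes of groups 8 to 13, 10 were higher in DL and 0 lower, and 10 adjusted over the list alone (camera adjusted p = 2.53e-18, and adjusted p = 0.0201 with an estimated correlation). Of 17 in groups 1 to 7, 3 were higher, and 7 adjusted over the list alone (adjusted p = 3.63e-08, and adjusted p = 0.0342 with an estimated correlation). Of 9 midbrain and oculomotor factors, 6 were lower in DL, and 7 adjusted over the list alone (adjusted p = 1.17e-10, and adjusted p = 0.0338 with an estimated correlation). En2 was at least 14.8-fold lower, and Otx1 and Otx2, which pattern the midbrain, were at 6.97 ± 2.68 against 109 ± 26.2 and 5.17 ± 3.75 against 67.6 ± 9.82. Irx5, an Iroquois factor, was at 11.9 ± 6.66 in DL and 386 ± 48.5 in OMN. Foxp1, a factor of limb motor columns, was at 1425 ± 617 in DL and 125 ± 110 in OMN, and Runx1 at 307 ± 232 and 12.2 ± 8.69.

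Slow and gamma motor neuron markers were lower in DL than in OMN in 3 of 7 cases, and 5 were lower and 1 higher adjusted over the list alone (camera adjusted p = 0.00446, but adjusted p = 0.164 with an estimated correlation). Htr1d was at 66.9 ± 8.60 in DL and 792 ± 144 in OMN, Esrrb at 74.7 ± 65.5 and 442 ± 44.3, and Esrrg at 695 ± 220 and 2562 ± 246. Of 16 GABA and glycine receptor genes 5 were higher and 1 lower in DL, and 6 and 1 adjusted over the list alone (adjusted p = 0.0169, but adjusted p = 0.253 with an estimated correlation and 0.0544 after quantile normalization), with Glra1 at 2850 ± 268 against 161 ± 72.7 and Glra3 at 214 ± 54.3 against 47.5 ± 12.5. Of 18 neuropeptide genes 3, Sst, Tac1 and Gal, were higher and 2 lower, and 6 and 3 adjusted over the list alone (adjusted p = 0.0143, but adjusted p = 0.253 with an estimated correlation). Sst stood at 4110 ± 422 in DL and 365 ± 99.1 in OMN. Pvalb was at 743 ± 89.6 in DL and 5221 ± 154 in OMN (log2 difference -2.79 ± 0.22, adjusted p = 0.00157). Kcng4, Grm3 and Epha6 were also lower in DL.

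Of 15 oligodendrocyte markers 3, Cldn11, Ermn and Ugt8a, were higher in DL, and 9 were higher and 2 lower adjusted over the list alone (camera adjusted p = 1.38e-05, but adjusted p = 0.0932 with an estimated correlation). Cldn11, a tight junction protein of myelin, was at 2012 ± 359 in DL and 867 ± 55.5 in OMN. Of 13 microglia markers 0 were called by limma, with 4 at an unadjusted p under 0.05, and 2 were lower adjusted over the list alone (adjusted p = 0.0299, but adjusted p = 0.268 with an estimated correlation and 0.0613 after quantile normalization). Of 6 Schwann cell and dorsal root ganglion markers 1, Pmp22, was higher in DL, and 2 adjusted over the list alone (adjusted p = 0.00638, but adjusted p = 0.253 with an estimated correlation). Of 8 inhibitory interneuron markers 2, the transporters Slc6a5 and Slc32a1, were higher in DL, and 3 were higher and 2 lower adjusted over the list alone (adjusted p = 0.0386, but adjusted p = 0.253 with an estimated correlation, 0.0548 after quantile normalization and 0.0853 after centring on the median). Slc17a6, the vesicular glutamate transporter of excitatory neurons, was lower at 202 ± 73.8 against 1124 ± 136. In all, limma called 247 genes higher and 298 lower in DL than in OMN. The count of 545 was 119 when only the DL and OMN arrays were fitted, 192 to 342 when any one L5 or OMN array was left out, 279 without DL replicate 1, 363 without DL replicate 3, 126 without DL arrays 1 and 3, 274 with the Gapdh ratio as a covariate and 196 with a pseudocount of 1. With arrays centred on their medians the share of higher genes was 60.6% in place of 45.3%, because the median of all genes moved from -0.036 to 0.111.

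**Figure D2:**
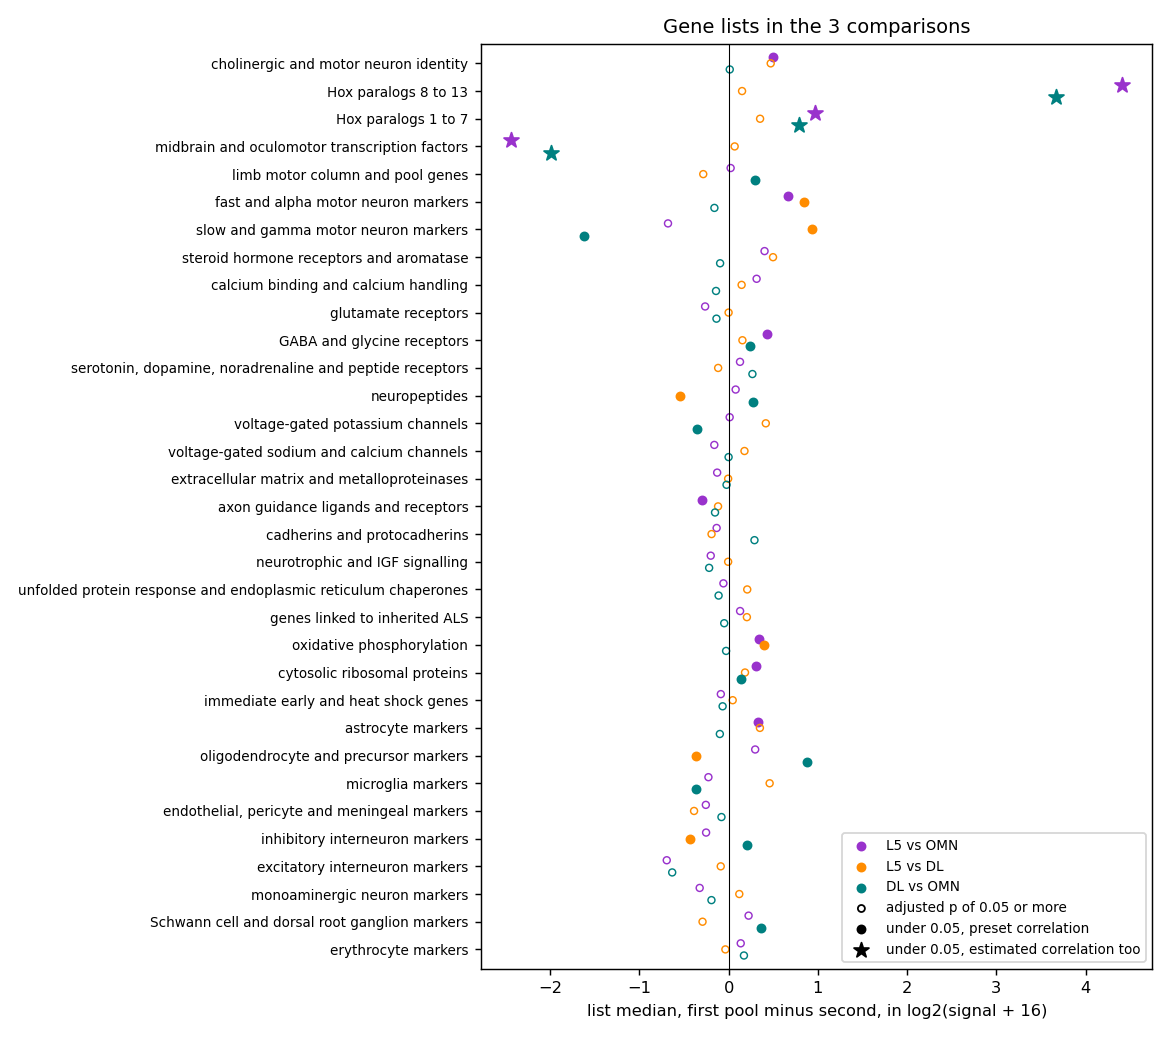
Median difference of each of the 33 gene lists in log2(intensity + 16) for L5 minus OMN, L5 minus DL and DL minus OMN, with open points for a camera adjusted p of 0.05 or more, filled points for a smaller one with the preset correlation and stars for a smaller one with an estimated correlation too. The stars are the Hox lists and the midbrain and oculomotor factors in the comparisons with OMN, with medians of 4.41 and 3.67 for Hox groups 8 to 13 and -2.43 and -1.99 for the midbrain factors.

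Genes that set L5 apart from both other pools were sought for the contrast between the limb level and the spared pools. With only 1 pool of a limb level, vulnerability cannot be told apart from other traits of L5. In a grouping with another pool in the place of L5, 172 genes differed from both others in the same direction. 42 genes were higher and 60 lower in L5 than in both OMN and DL. The balance turned to 69 and 57 with the mean of all probe sets and 208 and 158 with a trend and robust variances. Hsd17b2 was at 706 ± 103 (SD, n = 3) in L5 against 30.5 ± 40.1 in OMN and 27.3 ± 27.7 in DL, Aldh1a2 at 2284 ± 414 against 16.1 ± 16 and 207 ± 67.6, and Trhr at 2118 ± 476 against 111 ± 35.0 and 312 ± 139. Nts, Egln3, which is an oxygen-sensing hydroxylase, Il1f9, Arhgap9, Cited1, Mgam and Myh1 completed the 10 highest. Of these 10, Il1f9, a cytokine gene of the interleukin 1 family at 203 ± 39.1 in L5 against 6.87 ± 7.02 and 9.83 ± 5.50, was the one that kept its call against both pools in all alternatives chosen beforehand. Hsd17b2 lost its call against OMN and against DL in some of them, and Aldh1a2 and Trhr lost theirs against DL alone. Mmp9 was among the 42. In the other direction Sema3e was at 77.9 ± 31.3 in L5 against 1543 ± 238 and 2082 ± 96.9. Kcnj5, a potassium channel, was at the noise level in L5 and at least 12.4-fold and 11.3-fold higher in OMN and DL. Cartpt, Scn7a, Rnf152, Ndnf, Syt1, Gad2, Wdr48 and Cpne4 completed the 10 lowest, with Syt1, a synaptic calcium sensor, at 442 ± 112 against 2224 ± 335 and 3378 ± 482. Of these 10, Sema3e, Scn7a, Rnf152 and Gad2 kept their call against both pools in all alternatives chosen beforehand. Isl1 was at 598 ± 134 in L5, 2129 ± 45.7 in OMN and 2717 ± 414 in DL.

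Both comparisons use the same L5 arrays. Independent lists of the same lengths would share 4.95 genes in the same direction, against the observed 102. In 100 simulations in which no gene differed between the 3 pools, a mean of 0.01 and at most 1 were called. Without true differences hardly any gene can pass the threshold. These simulated counts therefore do not measure how much of the 102 comes from sharing the L5 arrays. 13 genes went in opposite directions. The log2 differences of the 2 comparisons correlated with r = 0.449 across genes, which are not independent replicates, where unchanged pools gave 0.5 on average. Their covariance was 0.147 against 0.048 in the simulations, a difference of 0.0985. The simulated pools shared the L5 arrays too, so this difference is what remained beyond sharing at the fitted spread. The 3 L5 arrays were too few to split, and a technical trait common to them can still be part of it. Against the mean of OMN and DL, limma called 194 genes higher and 204 lower in L5, 398 in sum. With no replicate block the counts were 187 for both pools and 693 for the mean. The count of 102 was 18 when each pair of pools was fitted alone, 15 to 18 without any one L5 array, 18 to 24 without any one OMN array, 47 without DL replicate 1 and 0 without DL arrays 1 and 3. The count of 398 was 36 or 37 without any one L5 array, 125 to 139 without any one OMN array, 239 without DL replicate 1, 261 without DL replicate 3 and 87 without DL arrays 1 and 3.

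**Figure D3:**
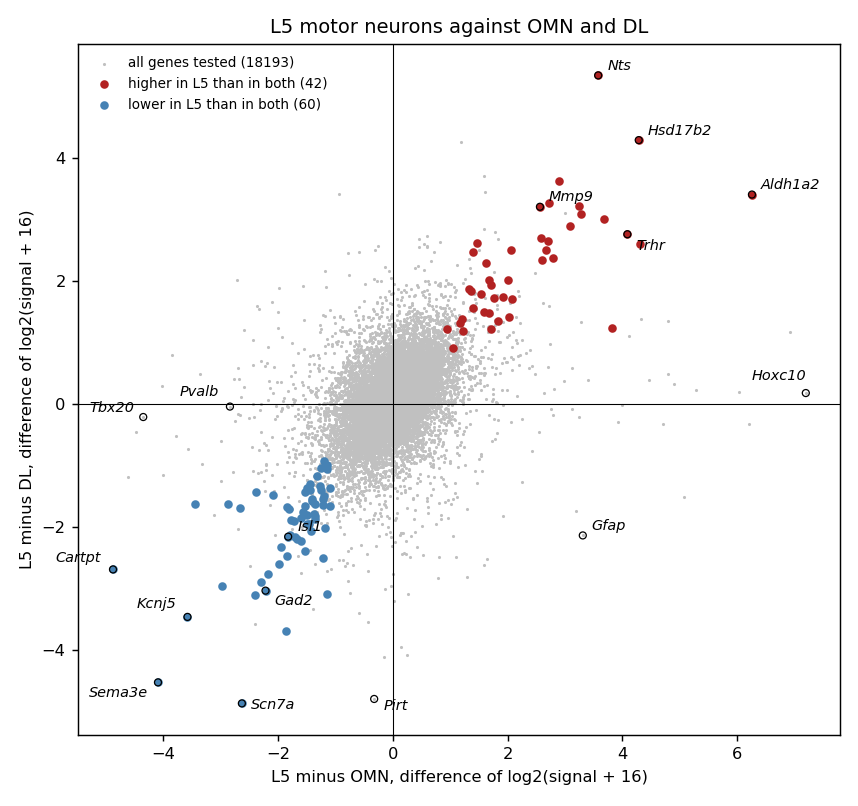
Difference of log2(intensity + 16) between L5 and OMN (horizontal) and between L5 and DL (vertical) for the 18193 genes, in grey, with the 42 genes higher in L5 than in both pools in red, the 60 lower in blue and open circles around the labelled genes. Nts, Aldh1a2 and Mmp9 lie at the upper right and Sema3e, Scn7a and Cartpt at the lower left, Hoxc10 and Pvalb lie near the horizontal axis, and both axes share the L5 arrays, which alone gives a positive relation.

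Several groups linked to vulnerability made no call for any gene between the pools. On the simulated arrays only 13.4% to 14.9% of planted log2 differences of 1 were recovered. A lack of calls therefore does not exclude differences of that size. Of 21 measured genes linked to inherited ALS, 0 were called by limma in the comparisons of the pools, with p adjusted over all genes or over the list alone. At an unadjusted p under 0.05 there were 5 for L5 against OMN, 6 for L5 against DL and 1 for DL against OMN, and the list medians were 0.13 for L5 against OMN, 0.20 for L5 against DL and -0.05 for DL against OMN (camera adjusted p = 0.189, 0.223 and 0.926). Fry asks whether the members as a set are shifted from 0 in one direction and does not set them against the other genes. By fry the same list had adjusted p = 0.012 and 0.00561 in the comparisons of L5 with OMN and DL. After quantile normalization these were 0.66 and 0.0853, with list medians of -0.045 and 0.07. After centring on the median they were 0.0467 and 0.301. Sqstm1, an autophagy receptor, was at 1734 ± 37.1 in L5, 1011 ± 114 in OMN and 1189 ± 262 in DL (adjusted p = 0.136 and 0.209 against L5). Of 24 genes of the unfolded protein response, 0 were called by limma in the comparisons of the pools, with 0, 2 and 1 at an unadjusted p under 0.05 (camera adjusted p = 0.582, 0.901 and 0.56). Of 71 genes of oxidative phosphorylation, 0 were called by limma, with 19, 24 and 0 at an unadjusted p under 0.05 in the same order, and their median was 0.34 higher in L5 than in OMN and 0.39 higher than in DL (camera adjusted p = 1.03e-09 and 1.35e-07, but adjusted p = 0.446 and 0.675 with an estimated correlation). With quantile normalization that median was 0.08 against OMN (adjusted p = 0.16) and 0.17 against DL (adjusted p = 0.0102). Of 44 cytosolic ribosomal protein genes 0 were called by limma between L5 and OMN, with 6 at an unadjusted p under 0.05. Their median was 0.30 higher in L5 (camera adjusted p = 0.000183, but adjusted p = 0.536 with an estimated correlation and 0.357 after quantile normalization). The highest intensity of a probe set other than the controls was 19727 to 23092 on the L5 arrays and 11813 to 15525 on the others. A difference of the L5 arrays at high intensity thus cannot be told apart from these rises of bright genes. Chodl and Gria2 had no call in any comparison, with Chodl, a marker of fast motor neurons, at 4895 ± 429 in L5, 3509 ± 163 in OMN and 4699 ± 102 in DL. The Chat probe set lay at 6.10 ± 6.01, 22.3 ± 2.02 and 15.6 ± 6.76, close to the noise level in all pools, so that it gives no measure of this cholinergic gene.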

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

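The counts of unnamed probe sets and the hybridisation controls were not part of the gene comparisons. They were looked at only after the results were seen, and the predictions for the counts of other splits were written after those counts had been seen. Groups of 3 arrays are too small for the test of outlying samples. Among 10092 probe sets that name no gene or several, 33 passed the threshold between L5 and OMN, 67 between L5 and DL and 86 between DL and OMN when all probe sets were tested together with limma. Of the 86, 26 were higher and 60 lower in DL. The hybridisation controls, bacterial and phage transcripts added in the same amount to each array by the maker's design, had a mean intensity of 32593 ± 3221 (SD, n = 3) in L5, 21265 ± 1865 in OMN and 20671 ± 4750 in DL, a ratio of 1.53 of L5 over OMN. The L5 arrays lay at 29353 to 35794 and the others at 16291 to 25721, without overlap. This technical difference coincides with every comparison of L5, including the genes that differed from both other pools. Its effect on them was not tested.

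For each comparison of a pair of pools, the 6 arrays can be split in 10 ways with 3 on each side, too few for a share under 0.05. The real split gave 392 genes for L5 and OMN, 459 for L5 and DL and 545 for DL and OMN, 1 split of 10 in each case, and the highest count of limma calls in any other split was 0. For L5 against the mean of the other pools, 2 of 100 groupings of the 9 arrays, the real one included, gave as many genes as the 398 observed, and the highest other count was 611. For genes that differed from both other pools, 2 of 100 groupings gave as many as 102, with 172 as the highest other. In both cases the higher count came from the 1 grouping drawn that held the same pools with another one in the place of L5. Among the rest the highest counts were 134 and 39. Those groupings mixed arrays of different pools, which puts the differences between pools into the spread and lowers the counts. They show that the pools differ, but cannot decide whether L5 stands apart more than another pool would.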

How the results depend on the processing

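No named gene reversed its direction under any alternative in which either value was called. Of the named and called genes, 38 of 85 between L5 and OMN, 13 of 77 between L5 and DL and 38 of 81 between DL and OMN kept their call in all alternatives chosen beforehand, and all of them kept their sign in every alternative run. Counts are given below for L5 against OMN (392), L5 against DL (459), DL against OMN (545), L5 against the mean (398) and both pools (102), where they moved by more than 1.5 times. Same-numbered arrays of different pools did not deviate together. The correlations of their deviations from the pool means lay between -0.021 and 0.027, and 4 of 9 arrays correlated best with their own number, so the numbers alone do not show a pairing. With no replicate block the counts were 805 for L5 against DL, 693 for the mean and 187 for both, and with the replicate block as a random effect (consensus correlation -0.0358) 745, 631 and 168. With only the arrays of the compared pools, the counts were 47 for L5 against DL, 119 for DL against OMN and 18 for both. Without genes below the median gene they were 775, 635 and 181 for L5 against DL, the mean and both, with fewer genes tested. A trend with robust variances gave 946, 1147, 872, 1073 and 366 in the order above, a pseudocount of 1 gave 101, 62, 196, 52 and 15, and a pseudocount of 64 gave 609, 836, 791 and 219 for all but DL against OMN. Array weights gave 677 for L5 against OMN, and all probe sets separately gave 865 for DL against OMN. Leaving out each array in turn gave 82 to 374, 61 to 254, 192 to 365, 36 to 309 and 15 to 78. The fits chosen after seeing the data gave 0, 126, 87 and 0 without DL arrays 1 and 3, and 90, 274, 153 and 33 with the Gapdh ratio as a covariate, for all but L5 against OMN. The balance of higher and lower genes also turned under some settings. Higher and lower genes were 257 and 248 between DL and OMN with quantile normalization, and 611 and 462 for L5 against the mean with a trend and robust variances. Centring on the median changed the share of higher genes from 49.7% to 39.4% between L5 and DL and from 45.3% to 60.6% between DL and OMN. The number of lists called by camera was 10, 6, 13 and 9 for L5 against OMN, L5 against DL, DL against OMN and the mean. An estimated correlation left 3, 0, 3 and 0. Quantile normalization left 6 for L5 against OMN, the filter at the median gene 6, 6 and 4 for all but L5 against DL, and fry gave 16 for L5 against OMN. Without DL arrays 1 and 3 the numbers were 3 for L5 against DL and 8 for DL against OMN, and leaving out each array in turn gave 9 to 12, 3 to 8, 8 to 13 and 6 to 10. Where no construction of the fit shows it, the cause was not tested. Near the noise level of 18.3 the arrays measure no level, which limits genes such as Hoxd9 in OMN to bounds.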

Other observations

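Some genes differed between pools although camera did not call the matrix, glutamate receptor or sodium and calcium channel lists. By fry the glutamate receptor list was lower in L5 and in DL than in OMN (adjusted p = 0.0366 and 0.0152). After centring on the median these fry values were 0.106 and 0.202. The 53 matrix genes had a camera adjusted p of 0.536 for L5 against OMN, 0.901 for L5 against DL and 0.926 for DL against OMN. Hapln1 and Hapln4, link proteins of hyaluronan nets around neurons, had intensities of 1759 ± 327 and 974 ± 118 (SD, n = 3) in L5, 2096 ± 162 and 706 ± 15.2 in OMN and 287 ± 68.9 and 163 ± 82.4 in DL, with log2 differences between L5 and DL of 2.56 ± 0.25 and 2.55 ± 0.31 (limma adjusted p = 0.00596 and 0.0113). The kainate receptor gene Grik1 was at 167 ± 13.1 in L5, 335 ± 27.9 in OMN and 1067 ± 276 in DL. Grm3, a metabotropic glutamate receptor, was at 341 ± 68.0, 650 ± 45.4 and 119 ± 25.5. The sodium channel subunit Scn4b was at 1732 ± 224 in L5, 988 ± 192 in OMN and 476 ± 242 in DL, with a call between L5 and DL alone. Reln, a secreted matrix protein, set OMN apart instead, at 123 ± 10.3 against 1187 ± 42.9 in L5 and 789 ± 94.9 in DL.

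Growth factor genes differed in several directions. Igf1 was at 259 ± 67.7 in L5 and 1258 ± 311 in OMN, and Igfbp5 at 717 ± 61.3 in L5, 2198 ± 210 in OMN and 2792 ± 1070 in DL. Igfbp3 was at 170 ± 39.2 in L5, 153 ± 35.5 in OMN and 490 ± 86.7 in DL. Fgf1 was at 1545 ± 149 in DL and 3418 ± 135 in OMN. Of 31 neurotrophic and IGF genes, 0 were higher and 2 lower in L5 than in OMN, 0 and 4 in L5 than in DL, and 4 and 3 in DL than in OMN (camera adjusted p = 0.17, 0.223 and 0.926).

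For the patterns weighed below, the tests of Gfap, of the genes known from sensory neurons and of the share of motor neuron RNA were chosen only after the result was seen, and the one test whose prediction was written before its value was known is that of RNA quality on the oligodendrocyte markers. The fit with the Gapdh ratio, and the fits with values raised to the noise level, were themselves added after the data had been seen. All are hypotheses from the data they were tested on.

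Gfap was higher in DL than in OMN, with a fitted log2 difference of 5.36 ± 0.30 after values under the noise level had been raised to it. More astrocyte material of one kind would raise other astrocyte genes alike, but the median difference of 13 other astrocyte markers was -0.12 with a bootstrap SD of 0.12, and they ranged from -0.92 to 1.11. Nor does the Gapdh ratio account for the whole difference. With it as a covariate the fitted difference was 5.74, and 5.70 ± 0.38 with raised values (limma adjusted p = 0.00516). That fit removes only what follows the ratio. DL array 2 had a ratio of 2.44, within the range of the other pools, but a low median intensity of 27.4. A difference in quality shared by all DL arrays therefore stays open. A difference between astrocytes of the cord and the midbrain, or expression tied to the pool, may remain as an untested biological candidate. Gfap was also called lower in L5, itself a cord pool, than in DL. A difference of cord and midbrain alone would not give that.

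Pirt, Scn11a and Scn7a, known from sensory neurons, were higher in DL than in L5, with a median fitted log2 difference of 4.14 after values under the noise level had been raised to it. Of 13 other sensory markers 8 were measured, limma called 0 of them (1 at an unadjusted p under 0.05), and the median difference of the 4 above the noise level in DL was 0.27 with a bootstrap SD of 0.15, a value low enough to speak against neurons of the dorsal root ganglion in the DL captures by the bound first set. That bound was set aside after the value was seen, because no marker exceeded a mean of 85.1 in either pool, near the floor of the arrays, and because Tac1, Gal and Ngfr, which sensory neurons also express, were higher in DL, so this source cannot be told apart from expression by the pool. The Gapdh ratio does not account for the whole difference of Scn11a. With the ratio as a covariate Scn11a stood at 4.43, and at 4.39 ± 0.29 with raised values (limma adjusted p = 0.0224). Nor does it for Scn7a, whose L5 values all lie under the noise level. The fitted difference of Scn7a with raised values was 4.14 ± 0.25 without and 4.03 ± 0.34 with the covariate (limma adjusted p = 0.0362). For both genes a difference in quality shared by all DL arrays stays open. Pirt, fitted at 4.88 with the covariate, went with raised values from 4.52 ± 0.49 to 4.40 ± 0.70 and lost its call (limma adjusted p = 0.064). Its error grew with 3 in place of 4 residual degrees of freedom. For Pirt even the part of RNA quality that follows the Gapdh ratio stays open. A biological difference between the pools was not tested.

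Oligodendrocyte markers were higher in DL than in OMN by a median of 0.88 over 15 genes. A lower share of motor neuron RNA in DL, made up evenly by all other cells, would raise their markers alike. The median of 45 astrocyte, microglia and vascular markers was -0.18, a gap of 1.06 with a bootstrap SD of 0.25. The bootstrap resampled genes and not arrays, so its SD does not measure the spread between captures. The gap speaks against an even gain of other cells only, and a lower share made up by oligodendrocyte material alone stays open. With the Gapdh ratio as a covariate the median was 0.78 with a bootstrap SD of 0.27, which does not settle whether RNA quality contributes. In that fit limma called 0 of the 15, with 10 at an unadjusted p under 0.05, and Cldn11 went from 1.19 ± 0.19 to 1.21 ± 0.26 and Ermn from 1.88 ± 0.28 to 2.11 ± 0.37, so wider errors and not smaller differences ended these calls. More oligodendrocyte material around DL neurons at this age, or a difference in the stage of myelination, may remain, and neither was tested.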
